A study of Drosophila melanogaster with 9 samples.

How the data were processed

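RNA was sequenced from ovaries of Drosophila melanogaster in 3 groups of 3 libraries: flies mutant for DPLG1, flies mutant for DPLG4, and control flies of the w1118 strain. Per the labels, the samples were total RNA and the 3 libraries of a group were biological replicates. Groups were taken from the sample titles, and the genotype labels give the same groups. The numbers in the titles (22, 5 and 7 for DPLG1, 15, 3 and 7 for DPLG4, 1, 2 and 3 for controls) were used only as replicate names, and what they stand for is not given in the sources used here.

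The values deposited by the authors were raw counts per gene, 1 file per library, with 17559 genes and 5 summary lines. Per the submitters' processing notes, the authors used FastQC, STAR 2.5, HTSeq and DESeq2, and the notes name the builds BDGP6 and GRCh37. The role of the human build, the annotation release and the strand setting of the counting are not given in the sources used here. Without a known strand setting, it is not known whether reads of genes that overlap on opposite strands were kept apart. The summary lines (reads that aligned to several places, were ambiguous or lay outside genes) stayed out of library sizes and tests. They held 11.5% to 13.8% of the total in 8 libraries and 72.0% in control replicate 1, where reads that did not align uniquely made up 70.7%, against 7.61% to 10.0% elsewhere.

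Gene names and positions came from the Ensembl annotation of build BDGP6.54, release 115, with synonyms from a RefSeq gene table. Of the identifiers in the files, 17253 were paired with a symbol and a position and 306 had no symbol. DPLG1 and DPLG4 were found among the gene synonyms, never by which counts fell.

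Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Of 13404 genes with any count, filterByExpr by group left 8427 tested genes, and libraries were scaled by TMM. A quasi-likelihood model with group as the only term was fitted to all 9 libraries with robust dispersion estimates, so that the groups shared 1 estimate of the spread (biological coefficient of variation 0.217). The contrasts were each mutant against control and DPLG1 mutant against DPLG4 mutant. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. CPM values are scaled by the TMM library sizes and given as mean ± SD over the 3 libraries of a group. The standard error (SE) of a log2 fold change is its size over the square root of the F statistic. Ratios for the targeted genes carry a 95% exact interval from the summed counts, and the floor of a library is 3 counts; both cover counting error only. Replicates of a group correlated at 0.976 to 0.994 (log CPM), and each pair differed by more than sampling noise.

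Choices made before the data were examined were the tests, the gene lists, the naming rule and the alternatives not described below as added. The 28 lists cover ovary cell types and processes, the nervous system, stress and nutrition, housekeeping complexes, and markers of other tissues that a dissection could hold. They were tested with camera at a preset correlation of 0.01 between genes, adjusted over the 28 lists of a comparison, and again with a correlation estimated from the data. For each list, members past 0.05 were also counted after adjustment over the list alone. After the matches were inspected, 4 synonyms that led to another gene than the one meant were dropped (Drs, nvd, don and dhod).

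Genes were named by a rule. Among called genes whose CPM did not overlap between the groups and whose mean log2 CPM was at least 1, the 6 with the largest and the 6 with the most negative log2 fold change were taken. Up to 6 higher and 6 lower genes with the smallest p and a name other than a CG or CR number were added, then up to 4 members with the smallest p of each list described, and the targeted genes. Other genes were chosen after their values were seen, and this is said where they appear.

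The test was tried on simulated counts drawn from the mean and dispersion of each of the 8427 genes and the library sizes, with 200 changed genes per comparison. Besides these 200, the 16 tested chorion genes were raised 2-fold, and they could not count as recovered or as false calls. For DPLG1 mutant against control it recovered 16.4% of 67 genes changed 1.5-fold, 59.7% of 67 changed 2-fold and 83.3% of 66 changed 4-fold. For DPLG4 mutant against control the shares were 20.9%, 64.2% and 84.8%, and for the direct comparison 13.4%, 61.2% and 89.4%. Among all calls, 4 of 110, 5 of 119 and 7 of 117 were false. Each gene was drawn independently and without a trend between libraries, so these shares hold only for such counts.

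The alternatives were size factors as in DESeq2, upper quartile scaling, no filter on low counts, a filter of a CPM of at least 1 in at least 3 libraries, the DESeq2 1.42.0 Wald test, a fit to the 6 libraries compared, library sizes without eggshell and yolk genes, and leaving out each replicate. Added after the data were seen were offsets that remove the trend of each library with exon length (97.9% of tested genes had a length; loess span 0.5), a gradient between libraries as a covariate, and counts of calls without genes on the chromosome of the targeted gene. The overlap of the mutants was set beside 100 simulations of unchanged groups against the same controls. The trend with length is given as Spearman's rho, across genes, of a library's deviation in log CPM with exon length. GC content was not analysed here.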

Results

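The data are counts of ovary RNA from Drosophila melanogaster mutant for DPLG1 or DPLG4, genes that derive from PIF transposases, and from w1118 controls, with 3 libraries in each group. Gene counts summed to 83830254, 51352072 and 44654859 in DPLG1 mutant replicates 22, 5 and 7, and to 63101252, 95751320 and 51512876 in DPLG4 mutant replicates 15, 3 and 7. Control replicates 1, 2 and 3 held 22289241, 93767502 and 18078883. The floor of 3 counts was 0.0313 CPM in the deepest library and 0.166 CPM in the shallowest. The comparisons ask how ovary transcripts of each mutant differ from those of control flies, and how the mutants differ from each other.

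Each targeted gene was nearly absent from its own mutant and present in the other groups. DPLG1 is CG12253 (FBgn0026148), a protein-coding gene on 2L at 10987806 to 10989241, plus strand. It had 0, 0 and 1 counts in the 3 DPLG1 mutant libraries and 8120 counts over the 3 controls, a control level 11000 times that of the mutant with a 95% interval of 1970 to 434000 (edgeR adjusted p = 1.13e-06). Its level was 60.9 ± 7.80 CPM in controls and 66.2 ± 9.58 CPM in DPLG4 mutants (SD, n = 3), a difference within the replicate spread (log2 fold change 0.12, SE 0.18, edgeR adjusted p = 0.768). DPLG4 is CG7492 (FBgn0035807), a protein-coding gene on 3L at 7651866 to 7654752, minus strand. It fell from 142 ± 26.02 CPM in controls to 1.57 ± 0.0950 CPM in DPLG4 mutants (edgeR adjusted p = 2.33e-06), so that 1.1% remained, a ratio of 90.9 with an interval of 81.4 to 102. In DPLG1 mutants CG7492 stood at 90.7 ± 17.6 CPM, which did not pass the test against control (log2 fold change -0.65, SE 0.17, edgeR adjusted p = 0.258).

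**Figure D1:**
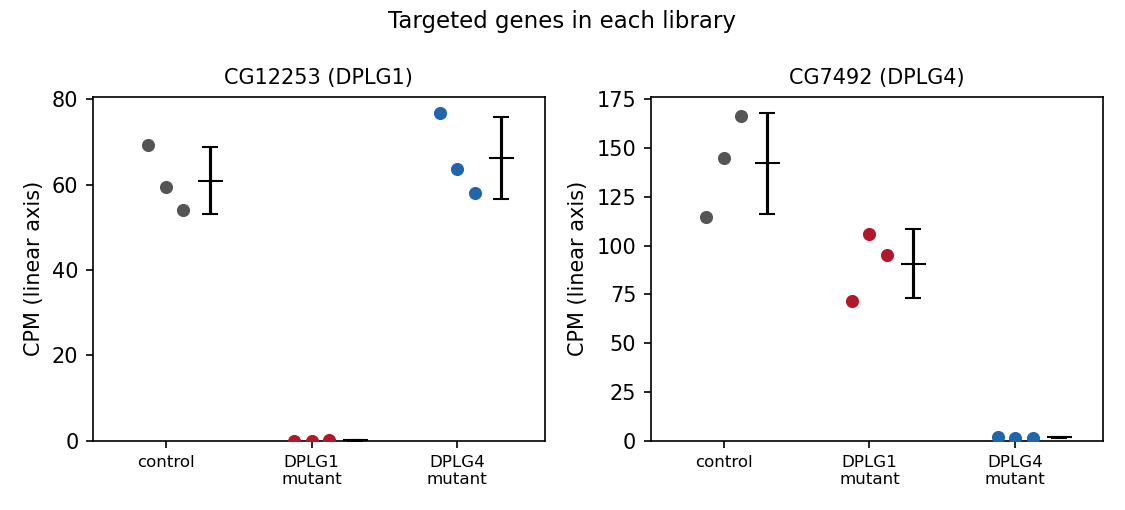
CPM of CG12253 (left) and CG7492 (right) on linear axes in each of the 9 libraries, as points by group, with the group mean and SD beside them. CG12253 was at 0.00741 CPM on average in DPLG1 mutants against 60.9 in controls, and CG7492 at 1.57 CPM in DPLG4 mutants against 142 in controls.

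In DPLG1 mutant ovaries the neighbouring capsid genes Arc1 and Arc2 were higher than in control. Arc1, whose product forms capsids that carry RNA between cells, was 4.73-fold higher (130.5 ± 21.8 against 27.6 ± 6.15 CPM, edgeR adjusted p = 0.00151), and Arc2 was 3.33-fold higher (24.1 ± 2.19 against 7.23 ± 0.301 CPM, adjusted p = 0.00151). Drep4, a nuclease of the DNA fragmentation factor family, was 2.52-fold higher (27.3 ± 1.62 against 10.8 ± 1.82 CPM, adjusted p = 0.0151). FBgn0042174, which had no symbol or position in the reference tables, was 5.20-fold higher (198 ± 6.11 against 38.2 ± 3.84 CPM, adjusted p = 1.47e-05). CG16957 was 29.6-fold lower (0.0962 ± 0.0427 against 3.04 ± 0.372 CPM, adjusted p = 0.00151).

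With the targeted gene, edgeR called 5 genes higher and 4 lower in DPLG1 mutants, of 8427 tested, and 601 higher and 830 lower at an unadjusted p under 0.05. The libraries of the groups did not overlap for 29.8% of genes, where chance gives 10% on average over splits. Genes that vary together between libraries can take a single split far from that average, so the share does not measure an effect of the mutation. The calls outside the naming rule, given after their values were seen, were FBgn0029128 (higher, 3.03 against 0.902 CPM) and asRNA:CR45330 and Adh (lower, at 0.183 against 1.86 and 0.00395 against 0.307 CPM). DESeq2 called 108 higher and 116 lower, among them all 9 edgeR calls. Without DPLG1 mutant replicate 22 or 5 or control replicate 2 or 3, 3 genes were called higher, and without DPLG1 mutant replicate 7, 12 were called lower. Without DPLG4 mutant replicate 7, which changes both the estimate of the spread and the tested genes (8701), 15 genes in place of 9 were called. Drep4 missed the threshold under 4 of 15 alternatives (adjusted p up to 0.0889) and overlaps CG44085 on the opposite strand; Adh and asRNA:CR45330 overlap other genes as well.

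Genes of the chorion, the outer eggshell layer secreted by late follicle cells, were higher in DPLG1 mutants as a list. Of 16 tested, 15 had a positive log2 fold change, with a median of 1.47 (camera adjusted p = 3.52e-10; adjusted p = 0.494 with an estimated correlation). None passed edgeR over all genes, 9 had an unadjusted p under 0.05, 7 passed when adjusted over the list alone, and DESeq2 called 6. Cp36 stood at 338 ± 20.9 against 109 ± 47.6 CPM, Cp16 at 80.1 ± 40.3 against 21.4 ± 9.18 CPM and yellow-g2 at 21.4 ± 9.76 against 4.16 ± 1.17 CPM (edgeR adjusted p = 0.228, 0.235 and 0.24). The lists of the vitelline membrane, the inner layer made earlier, and of yolk were not called (medians -0.23 over 10 genes and -0.35 over 4, adjusted p = 0.698 and 0.286). These medians depended on single libraries: -0.58 for both without DPLG1 mutant replicate 7, 0.0695 and 0.0047 without control replicate 1, -0.00523 and -0.23 without DPLG1 mutant replicate 22, and -0.43 for the vitelline membrane without control replicate 3.

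Ribosomal protein genes were slightly higher, with 79 of 82 positive and a median of 0.29 (camera adjusted p = 3.55e-12; adjusted p = 0.761 with an estimated correlation), such as RpS5b at 710 ± 79.5 against 527 ± 51.2 CPM; none passed edgeR over all genes or when adjusted over the list alone, 26 had an unadjusted p under 0.05 and DESeq2 called 1. Chromatin silencing genes had 37 of 43 negative and a median of -0.29 (adjusted p = 2.08e-05; adjusted p = 0.761 with an estimated correlation), with jing at 34.3 ± 7.85 against 70.0 ± 24.2 CPM and Jarid2 at 151 ± 37.7 against 291 ± 83.0 CPM. The insulin and nutrient list had 17 of 20 negative and a median of -0.40 (adjusted p = 0.00482; adjusted p = 0.494 with an estimated correlation), and the growth regulator Myc stood at 110 ± 7.27 against 156 ± 9.21 CPM (edgeR adjusted p = 0.24). In neither list did a member pass edgeR over all genes or when adjusted over the list alone; lower at an unadjusted p under 0.05 were 13 and 3, and DESeq2 called 0 and 1. Without DPLG1 mutant replicate 22 the ribosomal median was 0.18, and without control replicate 3 the insulin and nutrient median was -0.25. With upper quartile scaling the chromatin silencing and insulin medians were -0.148 and -0.255, still called (adjusted p = 5.71e-06 and 0.00228). Across genes, which are not independent replicates, deviations from the mean of the libraries followed exon length with rho from -0.396 to -0.0457 in the DPLG1 libraries and from -0.209 to 0.6 in controls. With that trend removed the ribosomal median was 0.0941 (adjusted p = 0.00108), the chromatin silencing median -0.23 (adjusted p = 0.0251), and the insulin and nutrient list was not called (adjusted p = 0.154).

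Immune genes were higher as a list, with 27 of 33 positive and a median of 0.99 (camera adjusted p = 0.000432; adjusted p = 0.761 with an estimated correlation). None passed edgeR over all genes, 8 had an unadjusted p under 0.05, 3 passed when adjusted over the list alone and DESeq2 called 3. The median was 0.65 without DPLG1 mutant replicate 22 and 2.77 without replicate 5, and 1.74, 1.58 and 2.06 without control replicate 1, 2 or 3. Genes were filtered anew in each of these fits, with 8550 to 8712 tested in place of 8427. The list members tested may thus differ, and these medians do not separate that from the library left out. With a filter of at least 1 CPM in at least 3 libraries the median was 0.36 and the list was not called (adjusted p = 0.214). The antimicrobial peptide genes AttA, at 1.73 ± 1.20 against 0.00357 ± 0.00618 CPM, and CecA1, at 0.532 ± 0.308 against 0.0476 ± 0.00838 CPM, had edgeR adjusted p = 0.167 and 0.253. The detoxification list had 30 of 42 positive (median 0.21, adjusted p = 0.0112; adjusted p = 0.761 with an estimated correlation), with the cytochrome P450 gene Cyp6d2 at 1.66 ± 0.575 against 0.516 ± 0.169 CPM; it was not called without DPLG1 mutant replicate 7 or control replicate 3 (adjusted p = 0.247 and 0.0605), or with upper quartile scaling (median 0.35, adjusted p = 0.0673). None of its genes passed edgeR over all genes or when adjusted over the list alone, 5 were higher at an unadjusted p under 0.05 and DESeq2 called 2. The gut list was called higher as well, with 14 of 16 positive (adjusted p = 0.00456; adjusted p = 0.761 with an estimated correlation); the counts of passing, unadjusted and DESeq2 genes were 0, 5 and 2. Its 43 genes under 1 CPM in every control summed to 1.91, 2.80 and 76.6 CPM in DPLG1 mutant replicates 22, 5 and 7, and to 1.84, 1.46 and 1.05 CPM in controls. Of 45 gut genes in the data only 16 were tested. Members such as alphaTry and Jon65Aiv, each with 0, 2 and 0 counts in controls, could pass the filter only through mutant libraries, which favours a positive sign.

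The mitochondrial ribosomal protein, oxidative phosphorylation and proteasome lists were called higher (medians 0.13, 0.15 and 0.16, camera adjusted p = 0.00314, 0.00157 and 0.00728) and the ecdysone list lower (median -0.40, adjusted p = 0.0296). With an estimated correlation the proteasome list had adjusted p = 0.494 and the other 3 had adjusted p = 0.761. With the length trend removed these 4 lists and detoxification were not called (adjusted p = 0.296, 0.977, 0.77, 0.77 and 0.091), and the medians of the first 3 turned to -0.058, -0.045 and -0.019. The early germline list was not called (adjusted p = 0.698). In it the differentiation factor bam stood at 62.0 ± 3.55 against 35.8 ± 1.39 CPM (edgeR adjusted p = 0.0588), and piwi, a piRNA pathway gene next to CG12253, at 241 ± 15.3 against 182 ± 10.2 CPM (edgeR adjusted p = 0.227). Nor were the piRNA and neuronal lists called (camera adjusted p = 0.213 and 0.771). The lists for maternal patterning, meiosis, cell cycle, follicle signalling, heat shock, muscle, fat body, hemocytes, female tract, testis, pigment and histones had adjusted p from 0.127 to 0.961.

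In DPLG4 mutant ovaries most called genes lay on 3L, the arm of CG7492. There pst (pastrel), a gene known for resistance to RNA viruses, was 33.9-fold lower (2.10 ± 0.369 against 71.1 ± 6.78 CPM, edgeR adjusted p = 1.63e-06). CG14985 was 8.07-fold and CG7565 6.10-fold lower (adjusted p = 1.05e-05 and 3.62e-05). CG4098 was 93.8-fold higher (10.9 ± 0.354 against 0.117 ± 0.0105 CPM, adjusted p = 1.05e-05), and CG12519 and CG10654 were 13.2-fold and 6.17-fold higher (adjusted p = 0.00292 and 0.00109). Gabat, which encodes the enzyme that breaks down GABA, rose 2.26-fold, from 169 ± 3.98 to 382 ± 25.0 CPM (adjusted p = 0.000607), and the hairpin RNA gene hpRNA:CR32205 was 3.07-fold higher (adjusted p = 0.0316).

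Called genes not placed on 3L included Map205, which encodes a microtubule-associated protein and was 4.37-fold lower (80.9 ± 21.7 against 354 ± 121 CPM, edgeR adjusted p = 0.0249). CG31431 was 2.80-fold lower and the mannosidase gene LManII 1.85-fold lower (adjusted p = 0.0417 and 0.0333). CG5245 was 3.61-fold, obst-B 2.51-fold, the translation factor gene MCTS1 2.10-fold, Drep1 1.91-fold and nom 1.89-fold higher (adjusted p = 0.00588, 0.0316, 0.0343, 0.0249 and 0.0282). FBgn0042174 was 3.14-fold higher (120 ± 5.54 against 38.2 ± 3.84 CPM, adjusted p = 9.43e-05). Of these genes, Map205, CG31431, CG5245 and nom lie on 3R, the other arm of the chromosome that carries CG7492. LManII and obst-B lie on 2L, Drep1 on 2R and MCTS1 on X, and FBgn0042174 has no position. Of 15 alternatives, obst-B missed the threshold under 10, CG31431 under 9, hpRNA:CR32205 under 8, MCTS1 under 7, LManII and nom under 6, Drep1 and Map205 under 5 and CG5245 under 2. The spans of CG4098, CG7565, CG10654, Gabat and hpRNA:CR32205, introns included, overlap those of Arts, Sarm, vih, Tom20 and CR33255 on the opposite strand. Because the counting strand is not known, it is not known whether their reads were kept apart.

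Altogether 23 genes were called higher and 13 lower, with 617 higher and 291 lower at an unadjusted p under 0.05. The groups did not overlap for 16.3% of genes, where chance gives 10% on average over splits. DESeq2 called 147 higher and 66 lower, among them all 36 edgeR calls. With only the 6 libraries compared, 7 were higher and 5 lower. Without DPLG4 mutant replicate 15 or 3, or control replicate 1, 2 or 3, there were 12, 8, 9, 5 and 7 higher and 7, 6, 8, 6 and 7 lower. The calls were also 20, 18 and 19 without DPLG1 mutant replicate 22, 5 or 7, with 8550, 8712 and 8677 genes tested.

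Leaving out the targets, 24 of the 34 placed DPLG4 calls lay on 3L, which held 19.1% of tested genes (odds ratio 10.3, Fisher's exact test, two-sided p = 8.48e-11, adjusted p = 3.05e-09 over arms, comparisons and tools). They comprised 16 higher and 8 lower genes, at distances of -5.48 to 17.28 Mb from CG7492. All 6 placed DPLG1 calls lay on chromosome 2, which carries CG12253 and 38% of tested genes (two-sided Fisher's exact p = 0.003, a test by whole chromosome that was chosen after the positions were seen). Of them, 4 were on 2L (adjusted p = 0.0382 for the arm), and Arc1 and Arc2 on 2R. Those on 2L lay at 2.25, 2.30, 2.41 and 3.63 Mb from CG12253, and Arc1 and Arc2 are neighbours. Fisher's test takes calls as independent, so with calls this close together its p-values may be too small, on 3L as well. Of the placed DESeq2 calls, 35.8% lay on 3L in DPLG4 mutants (19% of tested genes, adjusted p = 1.48e-07) and 21.9% on 2L in DPLG1 mutants (17.6% of tested genes, adjusted p = 0.216). PGRP-SD, a peptidoglycan receptor gene that overlaps CG7492 on the opposite strand, stood at 0.0200 against 0.600 CPM in DPLG4 mutants (edgeR adjusted p = 0.0127; it missed the threshold under 5 of 14 alternatives, with adjusted p up to 0.102).

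**Figure D2:**
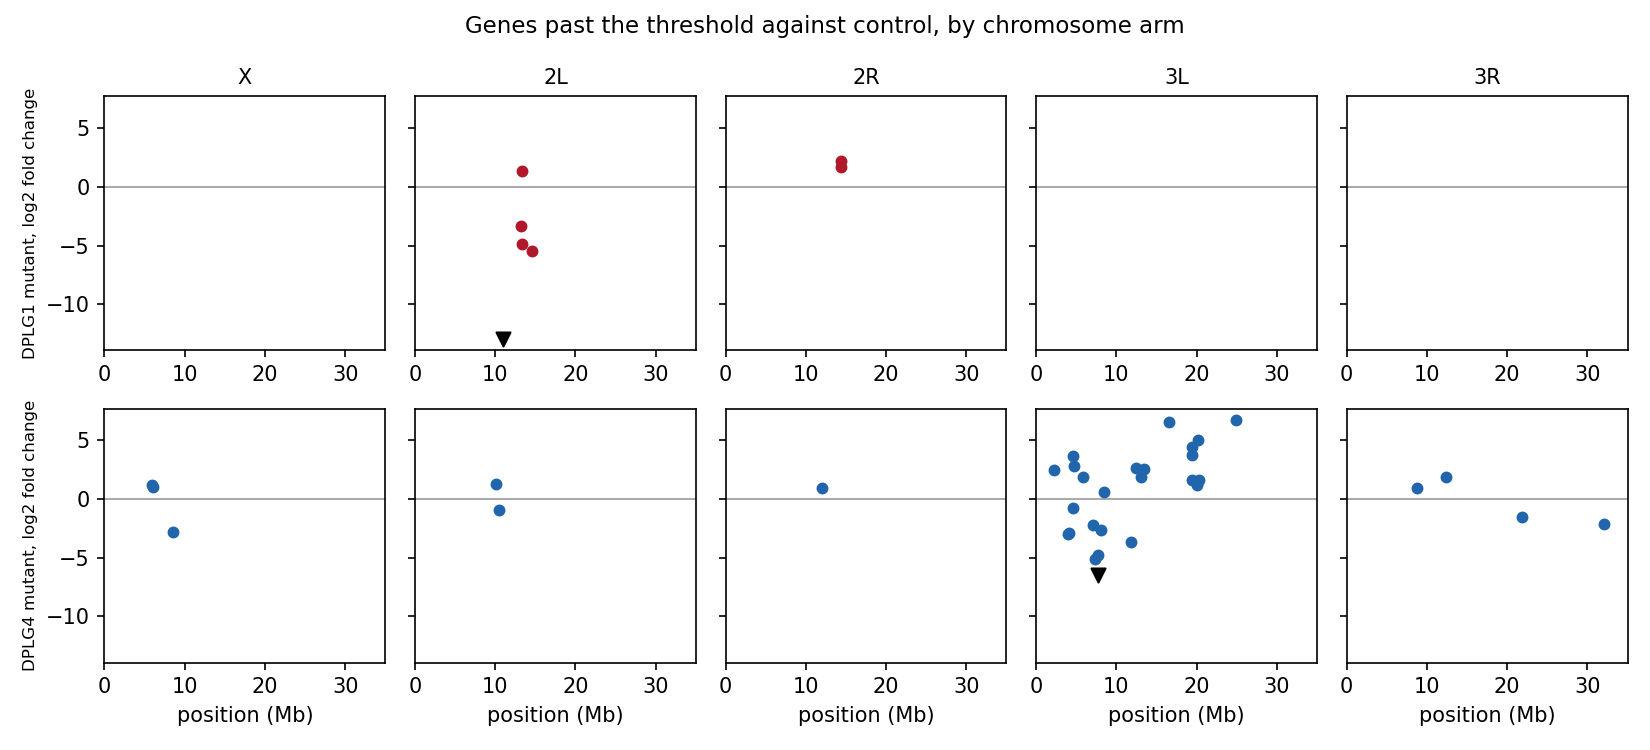
Log2 fold change against control of each called gene with a known position by start in Mb, for DPLG1 mutants (top) and DPLG4 mutants (bottom), 1 column per chromosome arm, with the targeted gene as a black triangle. Calls without a position are not drawn (FBgn0042174 in both mutants and FBgn0029128 in DPLG1 mutants). Besides the target, 24 points lie on 3L in the lower row, and all points of the upper row lie on 2L and 2R.

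Chorion genes were higher in DPLG4 mutants as a list: 16 of 16 were positive with a median of 1.36 (camera adjusted p = 6.34e-11; adjusted p = 0.691 with an estimated correlation). None passed edgeR over all genes, 10 had an unadjusted p under 0.05, 8 passed when adjusted over the list alone and DESeq2 called 4. Cp19 stood at 302 ± 119 against 89.7 ± 25.7 CPM and Cp15 at 704 ± 268 against 164 ± 60.7 CPM (edgeR adjusted p = 0.215 and 0.255). Vitelline membrane genes were higher too, with 10 of 10 positive, a median of 0.82 (camera adjusted p = 0.00675; adjusted p = 0.744 with an estimated correlation), and none past the threshold in edgeR over all genes, adjusted over the list alone, or in DESeq2, and 2 at an unadjusted p under 0.05. The median was 0.40 without DPLG4 mutant replicate 15, and the list was not called without control replicate 3 (adjusted p = 0.0769). Vm26Aa stood at 247 ± 69.8 against 129 ± 36.2 CPM. The yolk list was not called (median 0.38, adjusted p = 0.147; 0.742, 0.255 and 0.222 without control replicate 1, 2 or 3).

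**Figure D3:**
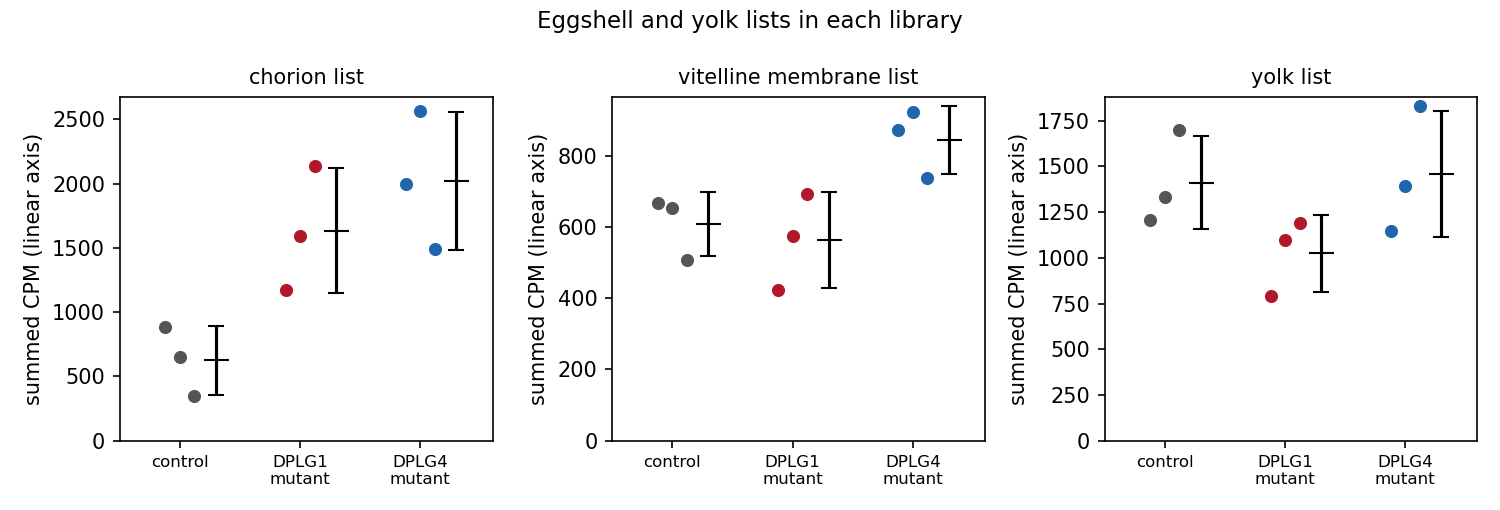
Summed CPM of the chorion, vitelline membrane and yolk lists on linear axes in each of the 9 libraries, as points by group, with the group mean and SD beside them. The chorion sum lay between 346 and 881 CPM in controls and between 1169 and 2566 CPM in the mutants.

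Ribosomal protein genes were higher in DPLG4 mutants, with 81 of 82 positive, a median of 0.37, none past the threshold in edgeR over all genes, 42 at an unadjusted p under 0.05, 5 when adjusted over the list alone and 8 in DESeq2 (camera adjusted p = 4.96e-22; adjusted p = 0.744 with an estimated correlation). RpS5b stood at 821 ± 72.7 against 527 ± 51.2 CPM (edgeR adjusted p = 0.0834). Chromatin silencing genes had 36 of 43 negative (median -0.20, adjusted p = 0.00675; adjusted p = 0.744 with an estimated correlation), with G9a at 331 ± 57.4 against 433 ± 36.5 CPM; none passed edgeR over all genes or adjusted over the list alone, or DESeq2, and 2 were lower at an unadjusted p under 0.05. Insulin and nutrient genes had 16 of 20 negative (median -0.25, adjusted p = 0.0117; adjusted p = 0.691 with an estimated correlation), and in that list Ilp5, an insulin-like peptide gene on 3L, stood at 0.0765 ± 0.0237 against 0.556 ± 0.185 CPM (edgeR adjusted p = 0.0581, past the threshold when adjusted over the list alone); it overlaps CG43897 on the opposite strand. Without DPLG4 mutant replicate 15 the medians were 0.20, -0.10 and -0.15, and the chromatin silencing and insulin lists were not called (adjusted p = 0.387 and 0.051). With a filter of at least 1 CPM in at least 3 libraries the insulin list was not called (median -0.20, adjusted p = 0.137). With upper quartile scaling the chromatin silencing and insulin medians were -0.107 and -0.164, both called (adjusted p = 0.00173 and 0.00469). Without control replicate 3 chromatin silencing was not called (median -0.12, adjusted p = 0.0969), and its median was -0.41 and -0.36 without DPLG4 mutant replicate 7 or control replicate 1. DPLG4 libraries followed exon length with rho from -0.499 to 0.435. With that trend removed the ribosomal median was 0.0995 (adjusted p = 1.1e-08), and the chromatin silencing and insulin lists were not called (adjusted p = 0.184 for both).

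The gut, mitochondrial ribosomal protein and oxidative phosphorylation lists were called higher in DPLG4 mutants (camera adjusted p = 0.0143, 0.0105 and 0.0105), each with adjusted p = 0.744 with an estimated correlation. Of the gut list 14 of 16 were positive, while its member LManII was called lower. Here too, members such as alphaTry could pass the filter only through mutant libraries, which favours a positive sign. The 43 gut genes under 1 CPM in every control summed to 17.4, 57.1 and 1.13 CPM in DPLG4 mutant replicates 15, 3 and 7. With the length trend removed the mitochondrial ribosomal median turned from 0.11 to -0.13 (adjusted p = 0.00618) and the oxidative phosphorylation list was not called (adjusted p = 0.223). Without DPLG4 mutant replicate 15 or control replicate 3, 4 lists were called in place of 8. The immune, meiosis and neuronal lists were not called (adjusted p = 0.14, 0.231 and 0.807), nor were the others, with adjusted p from 0.14 to 0.83.

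In the direct comparison, besides the targets, pst (38.0-fold), CG14985 (9.43-fold), CG7565 (6.90-fold), Arc1 (6.75-fold, 130.5 ± 21.8 against 19.4 ± 0.976 CPM), Map205 (4.08-fold) and Arc2 (3.10-fold) were higher in DPLG1 than in DPLG4 mutants (edgeR adjusted p = 6.52e-07, 5.21e-06, 1.77e-05, 0.000255, 0.0192 and 0.000968). Idgf2, a secreted imaginal disc growth factor, was 2.57-fold higher, Cyp6d4, a cytochrome P450, 2.41-fold, LManII 2.33-fold, Drep4 2.12-fold and Spindly, a kinetochore protein, 1.79-fold (adjusted p = 0.00543, 0.0138, 0.00436, 0.0135 and 0.0122). Lower in DPLG1 mutants were CG4098 (74.8-fold), CG16957 (46.7-fold), CG12519 (9.68-fold), CG10654 (4.93-fold), the cell surface protein gene dpr6 (4.10-fold), dao (3.99-fold), Drep1 (2-fold), Gabat (1.79-fold) and the mitochondrial carrier gene Bmcp (1.45-fold), with adjusted p from 6.85e-06 to 0.0217. The germline gene bam was 1.75-fold higher in DPLG1 than in DPLG4 mutants (62.0 ± 3.55 against 35.5 ± 4.50 CPM, adjusted p = 0.0138). Idgf2, Spindly and bam overlap CG5888, CG8852 and CG11854 on the opposite strand, and dpr6 overlaps several genes.

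In total 27 genes were higher and 26 lower in DPLG1 than in DPLG4 mutants, and 308 and 328 at an unadjusted p under 0.05. The groups did not overlap for 15.5% of genes, where chance gives 10% on average over splits. DESeq2 called 102 higher and 104 lower, among them all 53 edgeR calls. With only the 6 libraries compared, 14 were higher and 15 lower. Without DPLG1 mutant replicate 22, 5 or 7 or DPLG4 mutant replicate 3, 12, 17, 17 and 13 were higher, and without DPLG1 mutant replicate 22 or 5 or DPLG4 mutant replicate 3, 12, 13 and 17 were lower. Of 15 alternatives, Bmcp missed the threshold under 8, dao under 6, bam and Map205 under 5, Cyp6d4 and Spindly under 4, Drep1 and Drep4 under 3 and Idgf2 under 1.

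Vitelline membrane and yolk genes were lower in DPLG1 than in DPLG4 mutants as lists. Of 10 vitelline membrane genes, 9 were negative (median -1.10, camera adjusted p = 0.00109; adjusted p = 0.894 with an estimated correlation) and 1 passed when adjusted over the list alone; Vm26Ab stood at 38.7 ± 18.9 against 92.6 ± 6.12 CPM, and without DPLG4 mutant replicate 15 the median was -0.66. All 4 yolk genes were negative (median -0.73, adjusted p = 0.00738; adjusted p = 0.894 with an estimated correlation) and 2 passed when adjusted over the list alone, with the yolk protein gene Yp2 at 142 ± 33.7 against 242 ± 31.4 CPM. None of these passed edgeR over all genes; 6 and 2 were lower at an unadjusted p under 0.05, and DESeq2 called 1 of each list. The immune list was higher (median 0.28, adjusted p = 0.0362; adjusted p = 0.894 with an estimated correlation), and missed the threshold under 8 of 15 alternatives; of its genes PGRP-SD was called, 5 had an unadjusted p under 0.05 and 1 passed when adjusted over the list alone. Its median was -0.02, 0.67 and 0.03 without DPLG1 mutant replicate 22, 5 or 7, and 0.37, 0.51 and 0.46 without DPLG4 mutant replicate 15, 3 or 7. Genes were filtered anew in these fits (8520 to 8712 tested), so the members behind these medians may differ. The chorion list was not called (median 0.08, mean -0.03, adjusted p = 0.729), nor were the detoxification, meiosis and early germline lists (adjusted p = 0.206, 0.723 and 0.459) or the others (adjusted p from 0.156 to 0.823). Without DPLG1 mutant replicate 5 or DPLG4 mutant replicate 15, 3 or 7, there were 5, 7, 5 and 5 lists called in place of 3. With the gradient between libraries as a covariate, none of the 3 was called (vitelline membrane, yolk and immune, adjusted p = 0.0707, 0.06 and 0.107).

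Between the comparisons against control, 1 gene was called in both mutants in the same direction, FBgn0042174, against 0.02 for independent lists and 0 in simulations of unchanged groups; those gave 0.03 and 0.13 calls per comparison on average, so that 0 says little. It was higher in DPLG1 than in DPLG4 mutants (log2 fold change 0.73, edgeR adjusted p = 0.0122). DESeq2 called 44 genes in both in the same direction, against 1.8 for independent lists. Across genes, which are not independent replicates, the log2 fold changes of the mutants correlated at r = 0.768 against 0.546 simulated, with the same sign for 79.6% of genes against 67.2%. Their covariance was 0.362 against 0.0725 simulated, a difference of 0.29. With separate controls, 1 library for one mutant and the other 2 for the other, the covariance was 0.257 to 0.367 over the 6 ways, the correlation 0.39 to 0.607 and the share with the same sign 46.9% to 72.7%, a check added after the data were seen. In these 6 ways no control library served both mutants, so the covariance there does not come from a shared library. The share with the same sign fell to 46.9%, however, with control replicate 1 alone for DPLG4 mutants. The simulations held no trend between libraries, so the difference of 0.29 does not measure the part due to shared controls.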

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

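The 10 genes below differed between the mutants in the direct edgeR test, a test fixed before the data were examined, and stood above control in one mutant and below it in the other, each with an unadjusted p under 0.05, at an average log2 CPM of at least 1. Other called genes in opposite directions, such as pst and spirit, did not meet the condition on p or on level. All were compared with the same controls. On 2R, Arc1 differed by 2.75 on the log2 scale (adjusted p = 0.000255), with 2.24 in DPLG1 mutants and -0.51 in DPLG4 mutants against control. Ugt50B3 and CG30440, also on 2R, differed by 1.67 and 0.82 (adjusted p = 0.0162 and 0.0138; 0.93 and 0.34 in DPLG1 mutants, -0.74 and -0.49 in DPLG4 mutants). On 2L, Idgf2 differed by 1.36 (adjusted p = 0.00543; 0.73 and -0.63 against control) and LManII by 1.22 (adjusted p = 0.00436; 0.33 and -0.89 against control). On 3L, CG11263 and CG13295 differed by 0.97 and 0.59 (adjusted p = 0.00892 and 0.034; 0.56 and 0.26 in DPLG1 mutants, -0.41 and -0.33 in DPLG4 mutants), and CG2162 and dpr6 by -1.38 and -2.04 (adjusted p = 0.000828 and 0.00316; -0.70 and -1.12 in DPLG1 mutants, 0.67 and 0.92 in DPLG4 mutants). Cyp6d4 on 3R differed by 1.27 (adjusted p = 0.0138; 0.67 and -0.60 against control). Against control, Arc1 passed the threshold in DPLG1 mutants and LManII in DPLG4 mutants; the other 8 passed in neither.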

How the results depend on the processing

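The length-corrected offsets, the gradient between libraries as a covariate the counts without the chromosome of the target and the separate controls were added after the data were seen; the other alternatives were planned. No alternative turned the direction of a called named gene, and 28 of 49 calls of named genes were kept under every one of up to 15 alternatives, which do not include leaving out a library of the group outside the comparison. Without DPLG1 mutant replicate 22, 5 or 7, 20, 18 and 18 of all 36 DPLG4 calls were kept; without DPLG4 mutant replicate 15, 3 or 7, 8, 6 and 9 of 9 DPLG1 calls; and without control replicate 1, 2 or 3, 47, 39 and 43 of 53 direct calls. No list call held under every alternative. With an estimated correlation the lists called fell from 11, 8 and 3 to 0, 0 and 0, with 2, 2 and 1 at an unadjusted p under 0.05. The preset correlation was 0.01, and the estimates for the called lists were higher. They ran from 0.0361 to 0.673 in DPLG1 mutants, 0.0393 to 0.675 in DPLG4 mutants and 0.251 to 0.359 in the direct comparison. The preset p-values thus take genes as nearer to independent than these estimates do. What else contributed was not tested.

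DESeq2 called more genes than edgeR: 108 higher and 116 lower in DPLG1 mutants, 147 and 66 in DPLG4 mutants, 102 and 104 in the direct comparison, and 44 in both mutants; the cause was not tested. With only the 6 libraries compared, and so fewer samples for the spread, DPLG4 calls were 7 and 5 and direct calls 14 and 15. Without a filter on low counts, 7 genes were lower in DPLG1 mutants, 5 lists differed in the direct comparison and 2 genes were called in both mutants. Offsets that remove the length trend gave 9 lower in DPLG1 mutants, 25 lower in DPLG4 mutants and 46 higher in the direct comparison. For these as well the cause was not tested. Without genes on the chromosome of the target, which removes most calls by construction, 2 higher and 0 lower stayed in DPLG1 mutants, 5 and 2 in DPLG4 mutants and 3 and 0 in the direct comparison. These include genes without a position: both in DPLG1 mutants (FBgn0042174 and FBgn0029128), FBgn0042174 in DPLG4 mutants, and FBgn0042174 and FBgn0038035 in the direct comparison. Among all genes left after that removal, placed or not, edgeR had 566 lower in DPLG1 mutants and 72 in the direct comparison at an unadjusted p under 0.05. In both it called 0 lower, while DESeq2 called 73 and 18 lower.

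With the gradient as a covariate there were 1134 higher and 1865 lower in DPLG1 mutants, 738 and 1322 in DPLG4 mutants, 383 and 824 in the direct comparison, 1511 in both mutants, and 1 list in the direct comparison. That list is chromatin silencing (adjusted p = 0.0382, against 0.21 without the covariate), while the vitelline membrane, yolk and immune lists were not called (adjusted p = 0.0707, 0.06 and 0.107). Nor was the gut list against control (adjusted p = 0.0984 in DPLG1 and 0.28 in DPLG4 mutants). The proteasome list was called in DPLG4 mutants (adjusted p = 0.0336). That covariate was computed from residuals around the group means, so it cannot take up a part of the gradient that lies between groups. In 3 simulated draws without group effects it gave 0 to 44 calls. The draws may not match the real spread, so they leave the cause open.

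Leaving out each replicate gave 3 to 4 higher and 3 to 12 lower in DPLG1 mutants, 5 to 25 and 6 to 11 in DPLG4 mutants, and 12 to 27 and 12 to 28 in the direct comparison. The lists called were 8 to 11, 4 to 11 and 4 to 7. The called immune list, whose tested members may differ between these fits, changed sign in the direct comparison (-0.02 without DPLG1 mutant replicate 22, 0.668 without replicate 5). With length-corrected offsets so did the mitochondrial ribosomal protein, oxidative phosphorylation and proteasome lists in DPLG1 mutants (-0.058, -0.045 and -0.019) and the first 2 in DPLG4 mutants (-0.13 and -0.09). Lists and genes that were not called also changed sign, many lists with length-corrected offsets. Examples are the vitelline membrane and yolk lists in DPLG1 mutants (0.0695 and 0.0047 without control replicate 1), CG12253 in DPLG4 mutants (from 0 without DPLG4 mutant replicate 15 to 0.235 without control replicate 1, and -0.071 with length-corrected offsets) and HP1c in DPLG4 mutants (-0.006 with length-corrected offsets). With length-corrected offsets the follicle signalling, muscle and female tract lists were called in DPLG4 mutants (adjusted p = 0.00324, 0.0152 and 0.024), as was the immune list (adjusted p = 0.024), and the piRNA, muscle and female tract lists in DPLG1 mutants (adjusted p = 0.0471, 0.0457 and 0.041).

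No paired analysis was made, because what the numbers in the titles stand for is not given. They do not show which libraries, if any, belong together. Depth limited the low genes: in control replicate 3 a gene under 0.166 CPM has fewer than 3 counts.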

Other observations

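The tests of the length trend, of single libraries and of other splits were set before their results were seen; those of follicle cell share, of chromosomes and of gut genes were chosen after. Genes in this paragraph were chosen after their values were seen. Among the relatives of the targeted genes, CG32095 (DPLG3) stood at 58.7 ± 3.0 CPM in DPLG1 mutants, 58.5 ± 3.97 in DPLG4 mutants and 50.8 ± 1.89 in controls, and CG32187 (DPLG2) had 0, 5 and 3 counts over the libraries of these groups. The meiosis gene cort stood at 81.9 ± 3.29 CPM in DPLG4 mutants against 59.6 ± 3.68 in controls (edgeR adjusted p = 0.0864, past the threshold when adjusted over the list alone). The synaptic chaperone gene Csp stood at 161 ± 16.9 CPM in DPLG1 mutants against 246 ± 16.8 in controls (edgeR adjusted p = 0.146, past the threshold when adjusted over the list alone). The EGF receptor ligand gene vn, on 3L, was 3.77-fold higher in DPLG4 mutants than in controls (edgeR adjusted p = 0.013). Reads that did not align uniquely numbered 56325422 in control replicate 1 and 9721098 or fewer in each other library.

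The chorion list was higher in both mutants than in controls. The length trend does not account for it, since with the trend removed the medians were 1.32 and 1.15, the smaller being 0.848 of its uncorrected value, and both lists stayed past the threshold (camera adjusted p = 1.17e-09 and 2.51e-11; with an estimated correlation and no length correction, adjusted p = 0.494 and 0.691). Nor does a single library: the smallest median with a library left out was 0.918, in DPLG4 mutants without replicate 15. Both comparisons used the same controls, so the mutants do not give independent results. Without control replicate 3 the medians were 1.07 in DPLG1 and 1.01 in DPLG4 mutants. A larger share of follicle cells of all stages is argued against in DPLG1 mutants, where the chorion median exceeded the vitelline membrane median by at least 1.49 whichever library was left out, while in DPLG4 mutants the difference fell to 0.391 without control replicate 3 and the explanation stays open. A candidate explanation that was not tested is a larger share of late egg chambers, from the mutation, the age or feeding of the flies, or the dissection.

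The edgeR calls of each mutant lay mainly on the chromosome of its targeted gene (Fisher's exact test, two-sided, larger p = 0.003, which takes neighbouring calls as independent). With DESeq2 101 of 215 and 110 of 204 calls lay there, where 37.9% and 43% of tested genes lie (two-sided Fisher's exact p = 0.00666 and 0.00162). Of the 24 DPLG4 calls on 3L, 4.17% lay within 0.1 Mb of CG7492. Few genes of the arm lie that close, so this share hardly tests loss of neighbouring genes with the target. Loss would make genes lower, whereas 16 of the 24 were higher, which argues against it as the source of most of them. Within 1 Mb lay 5, with PGRP-SD, pst, CG7565 and CG14823 lower and CG13667 higher (log2 fold changes -4.80, -5.08, -2.61, -2.22 and 0.59). These counts do not show whether single neighbours were lost. The neighbours CG7506, Urm1, CG32373 and Ank2 had log2 fold changes of 0.12, 0.02, -0.08 and 0.37 (edgeR adjusted p from 0.751 to 0.975), while PGRP-SD was lower. With the gradient between libraries as a covariate the enrichment on the target chromosome did not pass (odds ratios 0.93 and 1.08, two-sided Fisher's exact p = 0.129 and 0.139). The placed calls there numbered 2927 in DPLG1 and 1997 in DPLG4 mutants, against 6 and 34 without the covariate. All 9 and all 36 calls made without it were kept. The enrichment was thus diluted by many further calls, whose cause was not found. Both a chromosome carried along with the mutated gene from another strain and regulation by the DPLG proteins stay open: that p describes the pattern and does not test its source, and no value here separates them for the calls on the target chromosome. Nor do the 6 placed DPLG4 calls off chromosome 3 decide, since effects of a linked chromosome on genes elsewhere were not tested.

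Gut enzyme genes were counted in some mutant libraries. Gut tissue carried over in the dissection may be the source: across 34 gut genes under 1 CPM in every control and counted in at least 1 of the 2 libraries compared, which are not independent replicates, the libraries of each mutant with the highest sum of these genes, DPLG1 mutant replicate 7 and DPLG4 mutant replicate 3, correlated at rho = 0.884 (permutation p = 1e-05, the smallest that 100000 permutations can give), with the trypsin gene alphaTry at 649 and 1100 counts. Another cause that raised the same genes would give such a correlation too, so it does not separate carry-over from induction. A first test of an effect of the mutation, on the whole list, left it open (the highest library of a mutant was at least 1.83 times its lowest), because LManII and Mal-B2, the 2 members at 1 CPM or more in controls, make up much of that sum. On the 43 genes under 1 CPM in every control, a set defined with its bounds after that result, the highest library of each mutant was at least 40.1 times its lowest, which argues against an effect shared by the libraries of a mutant.

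For 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In DPLG1 mutants and controls the real split called 9 genes and the highest of the others 0, so that 1 of 10 gave as many; at an unadjusted p under 0.05 edgeR gave 1431 genes for the real split and up to 1381 for the others. In DPLG4 mutants and controls the real split called 36, and 2 of 10 gave as many: DPLG4 mutant replicates 15 and 3 with control replicate 1 against the other 3 libraries called 1258. That split follows the trend with gene length (rho from -0.499 to -0.111 on one side and from 0.435 to 0.6 on the other), and it points to a structure of the samples apart from the groups. In the direct comparison the real split called 53 and the highest of the others 9, so that 1 of 10 gave as many; at an unadjusted p under 0.05 the real split gave 636 and another 1972.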
